A study of Danio rerio with 4 samples.

How the data were processed

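RNA from zebrafish embryonic hearts was measured on single-colour Agilent microarrays. Per the labels, embryos carrying a bmp2b transgene under the heat shock promoter hsp70l, Tg(hsp70l:bmp2b), and wild-type embryos were heat-shocked for 30 min at 37 °C at 18 hours post fertilization (hpf). Hearts were dissected by hand at 21 to 23 hpf and pooled. From each of the 4 samples, 200 ng of total RNA with an RNA integrity number above 8 was amplified once and labelled with Cy3. Both groups received the heat shock. There were 2 wild-type arrays, on slides 1 and 2, and 2 Bmp2b arrays, both on slide 3, so genotype and slide change together.

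The deposited values were spot intensities on a linear scale. The authors deposited a table of raw median intensity per spot, as its comment line states, with 43803 spots. A second table of the authors held processed intensities of the same spots. Its lowest values were 1.59 to 1.72 where raw intensities had a 5th percentile of 16 to 25, so a background had been taken off in a way not given in the sources used here. The series' value table held 43553 probes, all with the same values as the processed table, without the 50 probes that have 5 spots each; its medians were 30.7 and 28.2 for wild type and 4.22 and 14.4 for Bmp2b. Images were extracted with Agilent Feature Extraction, per the submitters' processing notes, which name no version. The tables name no control spots, and no control spot was therefore used or removed. Array medians differed in each table, so no scaling between arrays was seen. No background column and no flag for saturated spots was given in them, so saturation could not be checked.

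Analysis started from the raw median intensities. Each array was corrected by normexp with an offset of 50, without a background column, log2-transformed and quantile-normalized, and the spots of a probe were averaged. Background on an array was set at 2 times its 5th percentile of raw intensity. A probe was tested where it lay above background on at least 2 of the 4 arrays, which left 24454 probes. Bmp2b arrays were compared with wild type by limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05 on the adjusted p. A positive log2 fold change is a higher value in Bmp2b hearts. Errors of fold changes are standard errors from the limma fit.

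Probes were named through the platform's annotation: 23667 probes had 1 gene symbol, none had several, and 19936 were unnamed. Symbols of the platform annotation, which can be old, were looked up by gene identifier in the current zebrafish gene table (assembly GRCz12tu, used for names only), and 0 symbols changed. A gene was represented by its brightest tested probe, which gave 11383 genes, 4263 of them with more than 1 probe on test. A probe below background on both arrays of a group has only a bound there. For such a gene the fold is written as "at least", from the mean of the bright group against the mean of the dim group with each dim array's value raised to the lowest value of its probes above background.

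The comparison, the tests, 26 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named 22 genes of interest, then the 12 genes with the largest rise and the 12 with the largest fall past the threshold whose arrays did not overlap between groups, leaving out provisional names (clone names with a colon, LOC and Ensembl names, sequence accessions), then up to 3 members of each list with the smallest p among those past the threshold. Other list members in the text were picked from those past the threshold after their values were seen, and for genes past the threshold other tested probes that did not pass are given for genes named by the rule, and for other genes where they had the opposite sign. Lists were tested with camera (limma; preset inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over the 26 lists), and again with a correlation estimated for each list. The lists covered BMP targets, BMP pathway components, sarcomere, cardiac transcription factors, atrioventricular canal, extracellular matrix, Nodal and left-right genes, actomyosin, heat shock, endothelium, blood, neural tissue, epidermis, skeletal muscle, endoderm and yolk, neural crest, proliferation, p53, Wnt, FGF, Notch, retinoic acid, hox and posterior mesoderm, pericardium and epicardium, ribosomal proteins and the respiratory chain. A further 3 lists were added later and are given under the other observations.

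The 2 wild-type arrays were compared before averaging. Among 19 bright probes with 5 spots on each array, the spot means of the wild-type arrays differed by 0.0724 log2 units (root mean square), where the spread between spots on an array gives 0.124. The same figure for the Bmp2b arrays was 0.737 against 0.122. The wild-type arrays thus differed by less than the spread between spots gives, though that spread may overstate the noise between arrays. They are counted as 1 sample where a wild-type level is given, with no SD. The fit fixed in advance holds them as 2 arrays; fits with their mean as 1 sample, chosen after seeing the data, are given beside the counts. Nothing in the labels says that arrays of a group came from separate pools of embryos, so p-values measure the spread between these arrays, which can be technical.

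The test was tried on simulated data with the measured spread of each group (SD 0.0990 log2 units for wild type and 0.428 for Bmp2b), 24454 probes and 20 runs. With no change simulated it called 0 probes, while 7.23% had an unadjusted p under 0.05 (5.00% with an equal spread), and it recovered 0% of 2-fold and 0% of 4-fold changes when 100 probes of each size were changed. With an equal spread of 0.264 in both groups it recovered 55.2% of 2-fold and 100% of 4-fold changes, with a mean of 6.95 false calls. A list shifted by -0.5 was called in 20 of 20 runs at the measured spread, with 1 false call of another list. The list test was not tried with an equal spread. The number of arrays limits the precision, and at this number recovery differed between the measured and the equal spread. The simulation gave every probe of a group the same SD, while standard errors in the data varied between probes. In the data the same fit called 1668 probes higher and 2208 lower. The simulated recovery and false calls therefore cannot be carried over to the data.

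Alternatives changed the background correction, the scaling between arrays, the filter on dim probes, the variance prior, the threshold, the probe rule, the replicate block, and each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.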

Results

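Gene expression was measured in pooled hearts from zebrafish embryos at 21 to 23 hpf, the stage at which the heart cone turns into a tube displaced to the left. Hearts that overexpressed bmp2b from a heat-shock transgene (2 arrays, called Bmp2b here) were compared with heat-shocked wild-type hearts (2 arrays). Bmp2b is a secreted ligand of the BMP family, and the comparison asks which heart genes respond to it. The raw median intensity was 49 and 47 on the wild-type arrays, 35 on Bmp2b array 1 and 42 on Bmp2b array 2, and its 75th percentile was 445, 424, 93.5 and 250. Above background lay 57.4% and 57.1% of probes on the wild-type arrays, 34.1% on Bmp2b array 1 and 46.2% on Bmp2b array 2. Across probes, normalized values correlated with r = 0.998 between the wild-type arrays, r = 0.972 between the Bmp2b arrays, and r = 0.956 to 0.960 across groups. Of the probes tested, 32 differed at least 2-fold between the wild-type arrays and 1610 between the Bmp2b arrays.

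Transcripts of bmp2b itself were 60.2-fold higher in Bmp2b hearts, the largest rise of any named gene (log2 fold change 5.91 ± 0.17, SE; limma adjusted p = 0.0116). The normalized log2 level was 13.74 and 14.03 on the Bmp2b arrays against a mean of 7.98 in wild type, so it was higher on both arrays labelled as overexpressing it. With it rose ved, a homeobox repressor of the ventral embryo that acts below BMP, by 14.3-fold, and the msh-type homeobox genes msx1b and msx3 by 5.64-fold and 4.41-fold. Among the genes that fell most were those of the Nodal ligand ndr2 and the Nodal inhibitor lft1, which was 18.1-fold lower. Among heat shock genes hsp70l fell 6.01-fold, while the small heat shock protein gene hspb1 rose 7.24-fold. In the heart muscle the atrial myosin gene myh6 rose 3.83-fold, and the ventricular myosin heavy chain gene myh7 (vmhc) fell by 0.73 on the log2 scale.

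In total 1668 probes were higher and 2208 lower in Bmp2b hearts among 24454 tested (limma, Benjamini-Hochberg), of which 744 and 987 differed at least 2-fold. Taken by gene, 1025 were higher and 935 lower among 11383 tested, and 26 genes had probes called in both directions. At an unadjusted p under 0.05 there were 8952 probes. The arrays of the groups did not overlap for 67.6% of probes, where chance gives 33.3% for 4 separate arrays and 66.7% with the wild-type arrays as 1 sample. These counts rest on the closeness of the wild-type arrays, which differed by less than the spread between spots gives. With their mean counted as 1 sample, limma called 0 probes higher and 1 lower (2954 at an unadjusted p under 0.05), and 76 higher and 113 lower, or 51 and 46 genes, when the variance prior followed intensity (trend and robust). In both of these fits the spread comes from the 2 Bmp2b arrays alone. Genes that pass the fit with trend and robust are said below to hold with wild type as 1 sample; in the fit without, 0 genes passed (smallest adjusted p = 0.103, for bmp2b). Both Bmp2b arrays lay on slide 3 and the wild-type arrays on slides 1 and 2, so genotype and slide change together, and with slide as a random block at an assumed correlation of 0.5 limma called 0 probes higher and 1 lower (bmp2b adjusted p = 0.0794). Leaving out either wild-type array gave 0 probes higher and 1 lower, while 7121 higher and 8000 lower were called without Bmp2b array 1 and 7462 and 9565 without Bmp2b array 2, where the spread is that of the wild-type arrays alone. Scaling to the 75th percentile in place of quantile normalization moved the median log2 fold change of all probes from -0.06 to 0.28. It gave 493 probes higher and 378 lower, so the share of higher calls went from 43.0% to 56.6%. That share was 52.4% with only probes above background on all 4 arrays (1711 higher and 1552 lower), so the balance of directions also depends on the filter. The 89 named genes past the threshold and the 10 gene lists called kept their direction under each of the 4 other scalings tried, but with scaling to the 75th percentile 42 of these genes and 3 of these lists lost the call, and with an estimated correlation 0 of the lists passed.

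**Figure D1:**
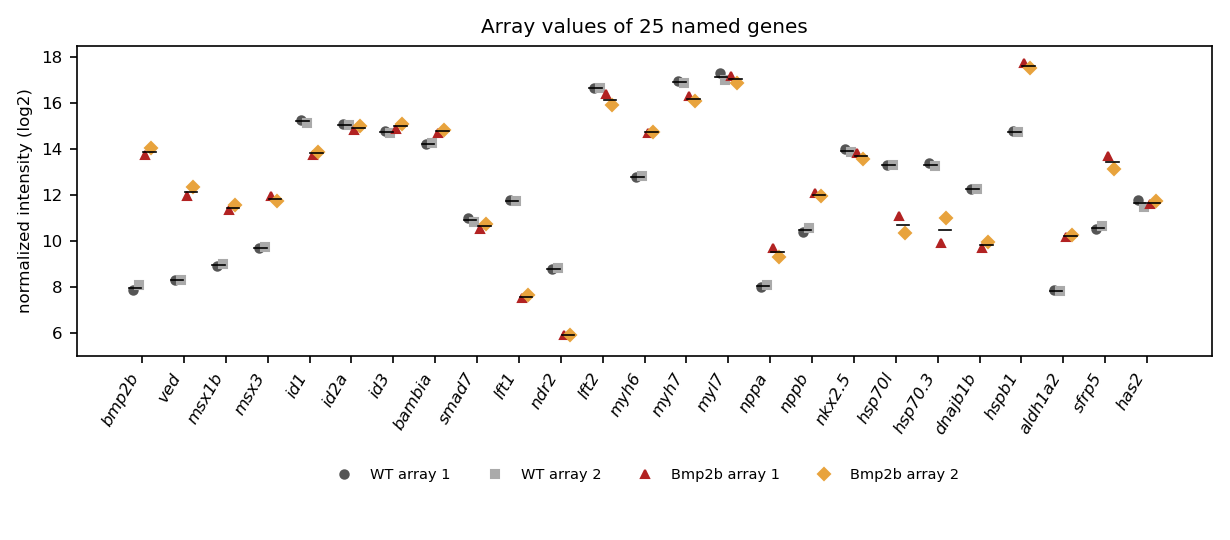
Normalized log2 intensity of 25 named genes on each array, with wild-type arrays as grey circles and squares, Bmp2b array 1 as red triangles and Bmp2b array 2 as orange diamonds; black bars are the means of the arrays of a group. bmp2b lies at 13.74 and 14.03 on the Bmp2b arrays and at 7.86 and 8.09 on the wild-type arrays, while lft1, hsp70l and id1 lie lower on both Bmp2b arrays and id2a, smad7, myl7 and has2 differ by less than 0.3 on average.

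Known BMP target and feedback genes were shifted upward as a list, yet most members did not pass. Of 28 measured members, 6 rose, 1 fell and 21 did not pass (7 and 1 adjusted over the list alone), with a median log2 fold change of 0.61. The median was 0.35 on Bmp2b array 1 and 0.70 on array 2, the array with more of the neural and epidermal markers, where 21 of 28 members were higher than on array 1. The members that rose were ved, msx1b, msx3, msx2b, tbx2a and gata2a, all transcription factors. The log2 fold change was 3.83 ± 0.16 for ved and 2.14 ± 0.14 for msx3, and msx1b was 5.64-fold higher, and all 3 hold with wild type as 1 sample. The member that fell was id1, which encodes an inhibitor of basic helix-loop-helix factors and is a common BMP readout (log2 fold change -1.40 ± 0.12, adjusted p = 0.0191). Its relatives id2a and id3 had log2 fold changes of -0.13 and 0.23 (adjusted p = 0.497 and 0.285; other id2a probes at 0.62 and 0.07 did not pass), and these signs turned in some of the other scalings, id2a with the processed intensities and id3 with scaling to the 75th percentile. Neither smad7, an inhibitory Smad (log2 fold change -0.27, adjusted p = 0.224), nor the pseudoreceptor gene bambia (0.53, adjusted p = 0.0555) passed. No probe named smad6a was measured. The list's camera adjusted p was 0.00934, with an adjusted p = 0.968 with an estimated correlation, and it was 0.0215 without Bmp2b array 2 and 0.175 with scaling to the 75th percentile.

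Among BMP ligands, receptors and antagonists, 4 of 27 measured genes rose, 2 fell and 21 did not pass (4 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.942). Its median was -0.08, its mean 0.14 and its camera direction down, and the median turned positive under 2 scalings. Next to bmp2b, the signal transducer smad1 rose by 0.80, and bmp6 and the antagonist nog1 also rose. The type I receptor gene acvr1l fell by 1.36, and twsg1b, for an extracellular BMP modulator, fell too. The other smad1 probes on test, at -0.19 and -0.01, and the other acvr1l probe, at -0.76, did not pass. bmp4, which is expressed in the heart tube, had a log2 fold change of -0.39 (adjusted p = 0.385).

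Nodal and left-right genes fell as a list, by a median of -0.39, with 3 of 15 measured members lower, 0 higher and 12 not passing (3 and 0 adjusted over the list alone). lft1, also called lefty1, fell by 4.18 ± 0.12 on the log2 scale (adjusted p = 0.0116). The Nodal ligand gene ndr2 was below background on both Bmp2b arrays and at least 4.18-fold lower (adjusted p = 0.0138), and elovl6, a fatty acid elongase gene, fell by 1.67. lft1 and ndr2 hold with wild type as 1 sample, but each rests on a single probe. A loss of these transcripts therefore cannot be told apart from a probe or transcript variant between the fish lines. lft2, or lefty2, the Nodal inhibitor gene of the left heart field, had a log2 fold change of -0.49 ± 0.21 (adjusted p = 0.178). The probe of spaw, the left-sided Nodal ligand, was below background on all 4 arrays. Camera gave the list an adjusted p of 0.0121, with an adjusted p = 0.805 with an estimated correlation; it was 0.118 without Bmp2b array 2 and 0.0673 with scaling to the 75th percentile.

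Sarcomere and contraction genes were lower as a list, but the members went both ways. Of 35 measured, 9 fell, 4 rose and 22 did not pass (10 and 4 adjusted over the list alone), with a median of -0.35. The genes that fell included myh7, with a log2 fold change of -0.73 ± 0.14 (adjusted p = 0.0440), the thin-filament gene tnnt2a (-1.14), the calcium-binding protein gene casq2 (-1.39), the titin gene ttn.2 and the potassium channel gene kcnh6a; another casq2 probe, at 0.72, did not pass. Those that rose were myh6 (1.94 ± 0.11, adjusted p = 0.0138), which holds with wild type as 1 sample, actn2b, and the natriuretic peptide genes nppa and nppb (1.47 and 1.53). myl7, a myosin light chain of all heart muscle, had a log2 fold change of -0.11 (adjusted p = 0.704). Camera gave an adjusted p of 0.0282, with an adjusted p = 0.968 with an estimated correlation. On Bmp2b array 2, the array with more of the neural and epidermal markers, 7 of the 35 members were higher than on array 1. The list's median against wild type was -0.12 on Bmp2b array 1 and -0.50 on array 2, and the adjusted p was 0.395 without array 2 and 0.0753 without wild-type array 1. It was 0.0611 with the mean over a gene's probes, 0.0522 with wild type as 1 sample (no trend or robust prior) and 0.310 with the processed intensities scaled to the 75th percentile, where the median was -0.21.

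Of 28 cardiac transcription factors, 4 rose, 3 fell and 21 did not pass (4 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.714), with a median of 0.03 that turned negative with scaling to the 75th percentile. Those that rose were tbx3a (log2 fold change 2.16) and tbx2a (1.16), T-box repressors of chamber genes, together with foxf1 and meis1a; another tbx2a probe, at 0.23, did not pass. The myocardial factor gene mef2ca fell by 1.96 on the log2 scale with 3 more probes that fell by 1.04 to 2.51, and tbx5a and meis2a fell too. nkx2.5 had a log2 fold change of -0.25 (adjusted p = 0.300) and tbx2b one of 0.20 (adjusted p = 0.388), and their second probes, at 0.43 and -0.35, did not pass either. The tbx2b value turned negative with scaling to the 75th percentile. Among 21 atrioventricular canal and valve genes, tbx3a, tbx2a and the fibronectin gene fn1b rose, 0 fell and 18 did not pass (3 and 0 adjusted over the list alone; camera adjusted p = 0.773, direction up). The median of this list was -0.03 and its mean 0.20, and the median turned positive with scaling to the 75th percentile.

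Extracellular matrix genes rose as a list, with 8 of 41 measured members higher, 2 lower and 31 not passing (12 and 3 adjusted over the list alone) and a median log2 fold change of 0.41. The increase included fn1b at 2.25 ± 0.16, which holds with wild type as 1 sample, the metalloproteinase gene mmp14a at 1.27, sparc, for a collagen-binding glycoprotein, at 1.49, and dcn at 1.90. Other probes of fn1b, sparc and dcn, at 0.36, 0.17 and -0.05, did not pass. The laminin genes lamb1a and lamb2 fell while lama1 rose (another lama1 probe, at -0.38, did not pass). has2, the hyaluronan synthase gene of the heart, had a log2 fold change of 0.02 ± 0.16 (adjusted p = 0.936), with a sign that turned with the scaling. Camera gave 0.0173, with an adjusted p = 0.805 with an estimated correlation; the adjusted p was 0.0793 without Bmp2b array 2 and 0.0591 with scaling to the 75th percentile, where the median was 0.69, and it was 0.68 with the processed intensities scaled this way.

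Actomyosin, adhesion and motility genes were not called as a list (camera adjusted p = 0.981), and the sign of their median, 0.04, turned under 2 scalings, with an adjusted p of 0.0391 downward under scaling to the 75th percentile. Of 51 measured, 3 rose, 2 fell and 46 did not pass (3 and 2 adjusted over the list alone). Higher were actn1 (1.58), an actin crosslinker gene, the myosin light chain gene myl9a (1.26) and the N-cadherin gene cdh2. Lower were cald1a, for caldesmon (-1.03), and myl9b. The non-muscle myosin heavy chain genes myh9a and myh10 had log2 fold changes of 0.70 ± 0.78 and 0.45 ± 0.23 (adjusted p = 0.555 and 0.236), and myh9a lay at 8.62 and 10.82 on the Bmp2b arrays against 9.01 in wild type.

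Heat shock and folding genes fell as a list, with 9 of 32 measured members lower, 1 higher and 22 not passing (12 and 1 adjusted over the list alone) and a median log2 fold change of -0.51. The inducible HSP70 genes hsp70l and hsp70.3 fell by 2.59 ± 0.28 and 2.85 ± 0.39, and their co-chaperone genes dnajb1b, dnaja2a, dnaja1 and bag3 fell as well, dnajb1b by 2.42. In the opposite direction, hspb1 rose by 2.86 ± 0.13 (adjusted p = 0.0138), and its second probe by 3.02. hsp70l, dnajb1b and hspb1 hold with wild type as 1 sample. Camera gave 0.00273, with an adjusted p = 0.805 with an estimated correlation. The median was -0.57 on Bmp2b array 1 and -0.43 on array 2, and -0.79 with the mean over a gene's probes, and the adjusted p was 0.00212 without array 2.

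Pericardial and epicardial markers were higher as a list, with a median of 1.14 and 7 of 15 measured members higher, 0 lower and 8 not passing (12 and 0 adjusted over the list alone). They included aldh1a2, for the enzyme that makes retinoic acid in mesothelium (2.37 ± 0.12), the secreted Wnt antagonist gene sfrp5 (2.85 ± 0.24), the transglutaminase gene tgm2b (1.33; another probe, at 0.31, did not pass), and cav1 and jam2b. aldh1a2 and sfrp5 hold with wild type as 1 sample. Camera gave 0.00273, with an adjusted p = 0.968 with an estimated correlation; the median was 1.27 on Bmp2b array 1 and 0.90 on array 2, and the adjusted p was 0.00111 without array 2. Retinoic acid pathway genes were called higher as a list, with 7 of 23 higher, 1 lower and 15 not passing (8 and 2 adjusted over the list alone) and a median of 0.50, which was 0.24 on Bmp2b array 1 and 0.97 on array 2, the array with more of the neural and epidermal markers. The median was 0.87 with scaling to the 75th percentile, 0.77 with cyclic loess, 0.92 with the processed intensities and 1.04 with these scaled to the 75th percentile, and 1.06 with only probes above background on all 4 arrays. Here aldh1a2, the receptor gene raraa and the responsive genes hoxb1a, hoxb2a and hoxb5a rose, and dhrs3b fell. Camera gave 0.0387, with an adjusted p = 0.968 with an estimated correlation, 0.463 without Bmp2b array 2 and 0.0653 without the filter on dim probes. Of 29 hox and posterior mesoderm genes, 3 rose, 1 fell and 25 did not pass (4 and 3 adjusted over the list alone; camera adjusted p = 0.622, and 0.0110 upward with scaling to the 75th percentile). osr1 rose by 1.51, and wnt8a fell by 2.52.

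Endothelial and endocardial markers were lower as a list by a median of -0.25, which was -0.12 on Bmp2b array 1 and -0.29 on array 2, the array with more of the neural and epidermal markers. Of 34 measured, 5 fell, 1 rose and 28 did not pass (5 and 1 adjusted over the list alone). lmo2, a hematopoietic and endothelial cofactor gene, fell 2.14-fold and the Notch ligand gene dll4 by 0.88 on the log2 scale. sox18 was below background on both Bmp2b arrays and at least 1.31-fold lower (adjusted p = 0.0211), and tal1 and cldn5a fell while stab2 rose. Camera gave 0.0315, with an adjusted p = 0.968 with an estimated correlation, and 0.438 without Bmp2b array 2, 0.0543 with the mean over probes and 0.0906 with the processed intensities scaled to the 75th percentile. Blood markers were not called (24 measured, 1 higher, 1 lower, 22 not passing; 1 and 0 adjusted over the list alone; camera adjusted p = 0.215). blvrb, a biliverdin reductase gene, rose 2.46-fold, and creg1 fell by 0.76.

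Markers of tissues around the heart separated the Bmp2b arrays from each other. Neural markers had a median of -0.84 against wild type on Bmp2b array 1 and 1.06 on array 2, and 30 of 35 were higher on array 2. Epidermal markers had medians of -0.06 and 1.61, and endoderm and yolk markers -0.10 and 1.18. The epidermal list was called higher (camera adjusted p = 0.00934, with an adjusted p = 0.968 with an estimated correlation), and without array 2 its adjusted p was 0.998. In it 4 of 26 measured members rose, 0 fell and 22 did not pass (4 and 0 adjusted over the list alone). These were the keratin genes krt8 and krt18a.1, also members of the pericardial list, icn and gsdmeb, with krt18a.1 at 1.71. In the neural list 3 of 35 rose, namely rx1, snap25b and mab21l2 (0.64, 0.88 and 0.60), 0 fell and 32 did not pass (0 and 0 adjusted over the list alone; camera adjusted p = 0.358). Other snap25b and mab21l2 probes, at 0.87 and 1.45, did not pass. Without array 2 the neural list was called lower (camera adjusted p = 0.0216), and without array 1 higher (8.75e-07). In the endoderm and yolk list 2 of 19 rose, the transferrin gene tfa (1.98; other probes, at 0.22 and 1.47, did not pass) and the cathepsin gene ctsla (0.76), 0 fell and 17 did not pass (2 and 0 adjusted over the list alone; camera adjusted p = 0.211). This list was called higher with scaling to the 75th percentile (camera adjusted p = 0.00732), with wild type as 1 sample without trend or robust (0.0309) and with the replicate block (0.0241).

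Neural crest and pharyngeal markers were higher as a list, with 5 of 27 members higher, 0 lower and 22 not passing (6 and 0 adjusted over the list alone) and a median of 0.81. snai2, a repressor of epithelial genes, rose by 2.75 ± 0.11 and holds with wild type as 1 sample. The mesenchymal homeobox gene prrx1a (1.72), the melanosome gene pmela (2.13), dct and the endothelin gene edn1 rose as well. Camera gave 0.00934, with an adjusted p = 0.968 with an estimated correlation; the median was 0.37 on Bmp2b array 1 and 1.23 on array 2, the array with more of the neural and epidermal markers, and the adjusted p was 0.205 without array 2. The median was 1.28 with scaling to the 75th percentile, 1.23 with the processed intensities scaled this way, and also over 1.5 times as high with only probes above background on all 4 arrays. Skeletal muscle markers were not called (31 measured, 1 higher, 3 lower, 27 not passing; 1 and 3 adjusted over the list alone; camera adjusted p = 0.981), with a median of 0.03, a mean of 0.07 and a camera direction down. acta1b fell by 1.53 (another probe, at -0.46, did not pass), pvalb4 was below background on both Bmp2b arrays and at least 1.56-fold lower, and smyhc2 was below background in wild type and at least 2.14-fold higher.

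**Figure D2:**
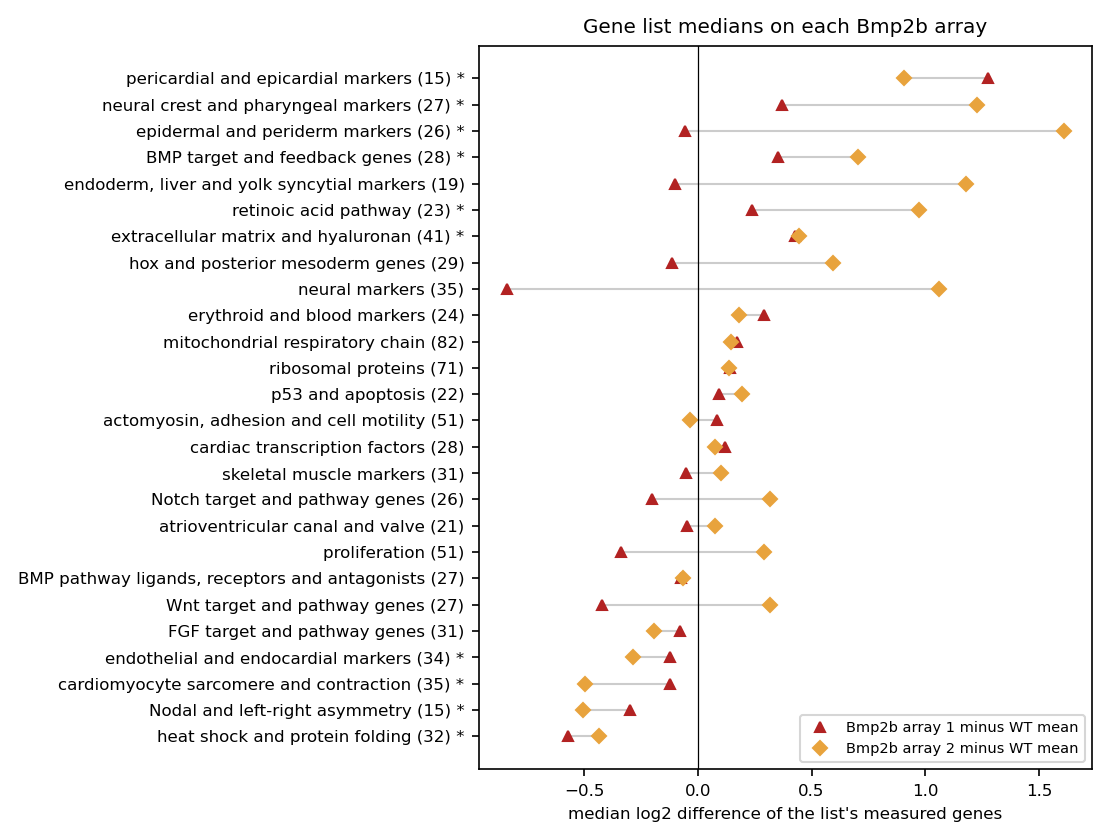
Median log2 difference from the wild-type mean over the measured genes of each list, for Bmp2b array 1 (red triangles) and array 2 (orange diamonds); the number of measured genes is in brackets and an asterisk marks lists with a camera adjusted p under 0.05 at the preset correlation, of which 0 pass with an estimated one. The heat shock list lies at -0.57 and -0.43, and the neural list at -0.84 and 1.06.

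Wnt, FGF and Notch lists were not called (camera adjusted p = 0.762, 0.157 and 0.942). Of 27 Wnt genes, 3 rose, 4 fell and 20 did not pass (3 and 6 adjusted over the list alone), and the median was -0.10 with a mean of 0.07 and a camera direction down. The median was -0.42 on Bmp2b array 1 and 0.32 on array 2, and turned positive under 2 scalings. The Wnt antagonist genes dkk1b and sfrp5 rose by 2.29 and 2.85 and the receptor gene fzd7a also rose. The ligand genes wnt8a and wnt11, prickle1b and lef1 fell, wnt8a by 2.52. Of 31 FGF genes, 1 rose and 3 fell with 27 not passing (1 and 1 adjusted over the list alone), namely fgfr3 at 0.96, the feedback inhibitor gene spry2 at -0.92, junba at -0.64 and etv5b. The FGF list was called lower with scaling to the 75th percentile (camera adjusted p = 0.0380). Of 26 Notch genes, 1 rose and 3 fell with 22 not passing (1 and 3 adjusted over the list alone). The ligand genes jag1b and jag2b had log2 fold changes of 1.06 and -0.89, and dll4 and notch2 also fell. Other probes of jag1b, at 0.03 and 0.63, and of notch2, at 0.47, did not pass, while those of jag2b fell as well.

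Proliferation genes were not called as a list (camera adjusted p = 0.298, and 0.00574 downward with scaling to the 75th percentile, and 0.000489 downward without Bmp2b array 2). Of 51 measured, 3 fell, 0 rose and 48 did not pass (0 and 0 adjusted over the list alone). The replication licensing gene cdt1 fell by 0.97 and the cell cycle genes ccne2 and cdc20 by 0.73 and 0.70. The median of the list, -0.06, was -0.34 on Bmp2b array 1 and 0.29 on array 2, and turned positive with the processed intensities scaled to the 75th percentile (0.02) and with only probes above background on all 4 arrays (0.03). p53 and apoptosis genes gave 2 higher, 3 lower and 17 not passing of 22 (2 and 3 adjusted over the list alone; camera adjusted p = 0.942). The pro-apoptotic gene bbc3 (puma) rose 2.46-fold and casp9 by 1.04, while gadd45ba fell by 2.03 (another probe, at -0.29, did not pass) and apaf1 and foxo3b fell too. The median of the p53 list was 0.09 and its mean -0.03, and the median turned negative with scaling to the 75th percentile. Ribosomal protein genes gave 5 higher, 1 lower and 65 not passing of 71 (2 and 0 adjusted over the list alone; camera adjusted p = 0.316). rps10, rpl30 and rpl14 rose by 0.87 to 0.93, while the second probe of rpl30, at -0.23, did not pass. Respiratory chain genes gave 8 higher, 4 lower and 70 not passing of 82 (14 and 10 adjusted over the list alone; camera adjusted p = 0.264). ndufa1 fell by 2.28, and cox6b1 and sdhaf3 rose by 2.21 and 1.13. The medians of the ribosomal and respiratory chain lists, 0.09 and 0.17, turned negative with scaling to the 75th percentile, where both lists were called lower (camera adjusted p = 0.0301 and 0.0203).

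Apart from bmp2b, ved, hspb1 and sfrp5, the genes with the largest rise were, with provisional names such as zgc:163030 (3.55) left out, clu (log2 fold change 4.16), for the secreted chaperone clusterin, sesn2 (3.55), a stress-induced regulator of growth signalling, and igfbp1a (3.52), for a secreted binder of insulin-like growth factors. They were followed by the fatty acid-binding protein gene fabp4a (3.32), the neutral amino acid transporter gene slc1a4 (3.24), the iron-sulfur cluster gene isca1 (2.96), olfm2a (2.93) and triqk (2.90). Falls were ranked likewise, with unnamed probes and provisional names left out and each gene taken by its brightest probe. Apart from lft1, ndr2 and hsp70.3, the largest in this ranking were those of tmem88a (-3.32), for a membrane inhibitor of Wnt signalling, and srl (-3.07), for a calcium-binding protein of the sarcoplasmic reticulum. The others were atp8b5a (-3.04), raver2 (-2.87), cs (-2.83), for citrate synthase, plppr5b (-2.83), wnt8-2 (-2.80), osr2 (-2.76) and mhc1lia, which was below background on both Bmp2b arrays and at least 5.08-fold lower. All of these hold with wild type as 1 sample (trend and robust), with adjusted p from 0.00513 for clu to 0.0247 for triqk, and 0 pass without trend and robust (0.189 for clu, 0.193 for triqk). Other probes of these genes did not all pass: they had log2 fold changes of 0.49 for sesn2, -0.65 for olfm2a, -0.14 for triqk, -0.23 for raver2 and -0.79 for cs. Of these, the triqk and raver2 probes lay below background on both Bmp2b arrays and those of sesn2 and cs on 1, which limits what they show. Larger falls lay outside the ranking. Dimmer probes of hnrnpaba and h3f3d fell by 3.75 and 3.35 (their other tested probes were at -0.38 and -1.66), and unnamed probes fell by up to 8.62.

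**Figure D3:**
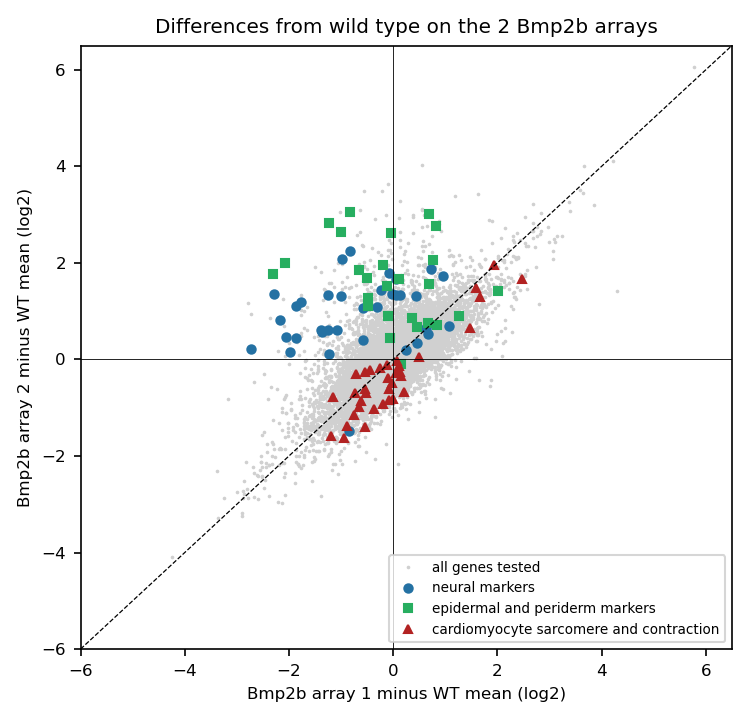
Difference from the wild-type mean on Bmp2b array 1 (horizontal) and array 2 (vertical), in log2 units, for 11383 genes (grey dots), with neural markers as blue circles, epidermal markers as green squares and sarcomere genes as red triangles; the dashed line marks equal values. Neural and epidermal markers lie mostly above the line, 30 of 35 and 22 of 26, and sarcomere genes mostly below it, with 7 of 35 above.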

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

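The alternatives with wild type as 1 sample, with processed intensities scaled to the 75th percentile and with an assumed slide correlation were chosen after seeing the data; the planned slide block was not run, since duplicateCorrelation gave no estimate. Probes, then genes, higher and lower are given in that order, against 1668 and 2208 probes, 1025 and 935 genes, and 6 lists up and 4 down. Background correction, offset, cyclic loess, both filters on dim probes, and trend and robust left these counts within 1.5 times. Scaling to the 75th percentile gave 493 and 378, 300 and 181, and 8 lists down, with 382 of 1960 gene calls kept. It turned the medians of the actomyosin (-0.18), ribosomal (-0.094) and respiratory chain (-0.14) lists. The authors' processed values, quantile-normalized, gave 1068 probes higher and 630 and 530 genes; scaled to the 75th percentile they gave 824 and 1217, 485 and 392, and 2 lists down. In these 3 settings the cause was not tested. A stricter call gave fewer by construction: 662 and 872, 408 and 373 with treat against 1.2-fold, and 744 and 987, 461 and 418 at 2-fold. The mean over probes gave 2 lists down, without the sarcomere and endothelial lists, and an estimated correlation 0 up and 0 down. Wild type as 1 sample gave 0 and 1, 0 and 0 (bmp2b 5.91, limma adjusted p = 0.103), and with trend and robust 76 and 113, 51 and 46. Slide with an assumed correlation of 0.5 gave 0 and 1, 0 and 0 (bmp2b 5.91, limma adjusted p = 0.0794), with 5172 probes at an unadjusted p under 0.05.

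Leaving out each array gave 0 to 7462 probes higher, 1 to 9565 lower, 0 to 4073 genes higher, 0 to 4079 lower, 2 to 8 lists up, 3 to 5 down, and a bmp2b change of 5.76 to 6.06 (limma adjusted p = 0.00300 to 0.114). The low counts of probes and genes came without either wild-type array and the high ones without either Bmp2b array, when a lone array is assumed to vary like the other group; without Bmp2b array 2 there were 2 lists up and 3 down. The neural list's median went from -0.84 without Bmp2b array 2 to 1.06 without array 1, and the change of myh9a from -0.39 to 1.80. With the replicate block 1347 and 1709 probes and 820 and 727 genes were called, with 7 lists up and 4 down. Same-numbered arrays deviated together with r = 0.0935 across probes. As the wild-type arrays differed so little, this cannot tell whether equal numbers pair the samples. Of 89 named genes called, 42 lost the call with scaling to the 75th percentile, 89 with wild type as 1 sample and 55 with trend and robust as well. The dimmer Bmp2b arrays limit what can be seen of weak genes, as 34.1% and 46.2% of probes were above background there.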

Other observations

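In this part the added gene lists, the tests of the tissue markers, including those outside the fixed lists, and of the heat shock genes, the raising of values to the floor, and the comparison of other probes at 4-fold were chosen after the results were seen. Genes already seen were left out of the added lists.

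Genes of the amino acid response, many of them targets of the factor Atf4, included further rises, as did sesn2, slc1a4 and igfbp1a, which are known to respond to Atf4. Of 31 other measured members, 9 rose, 1 fell and 21 did not pass. stc2a, for a secreted glycoprotein, rose by 1.93 on the log2 scale, the mTORC1 inhibitor gene ddit4 by 1.71, and the amino acid transporter genes slc7a5 and slc3a2b by 1.43 and 0.98. The serine synthesis genes phgdh and psat1 rose by 0.75 and 0.84. Of the tRNA synthetase genes, iars1 and gars1 rose by 0.98 and 0.65, while the others measured, at -0.28 to 0.11, did not pass. chac1, for a glutathione-degrading enzyme, fell by 1.32, and atf4a, at 0.21, ddit3, at -1.23, and trib3, at -0.19, did not pass. As a list these genes did not pass the threshold of 0.05 set beforehand (median 0.21, camera adjusted p = 0.0525 over the 3 added lists, adjusted p = 0.586 with an estimated correlation). That value was so close to the threshold that the question was left open, a margin set after it was seen. Among 28 endoplasmic reticulum chaperone and folding genes 4 rose and 3 fell (camera adjusted p = 0.823), and among 18 hypoxia genes 3 rose, p4ha1b by 1.81, and 0 fell (camera adjusted p = 0.124), so neither list passed. With wild type as 1 sample stc2a had an adjusted p of 0.0671 (limma, trend and robust).

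Neural and epidermal markers were higher on Bmp2b array 2 than on array 1, in 52 of the 61 pooled (median difference 1.65), and the epidermal keratin gene krt4 lay at 11.73 on array 1 and 15.78 on array 2 against 12.96 in wild type. Of the epidermal markers called higher against wild type, krt8, krt18a.1 and icn went the other way between the arrays. They lay at 17.81, 15.41 and 15.05 on array 1 and at 17.45, 14.81 and 14.91 on array 2. Skin and neural tissue taken along with the hand-dissected heart is a candidate explanation, tried on markers outside the fixed lists whose difference had not been looked at: 18 skin markers had a median of 0.62 with 13 higher on array 2, and 44 neural markers one of 1.29 with 42 higher, where random lists of the same wild-type level reached 0.279 and 0.181 at the upper end of their central range. Another candidate is the dimmer signal of array 1. The 10000 random lists matched to the pooled markers centred on -0.014 and reached 0.136 at the same upper end. Quantile normalization gives both Bmp2b arrays the same distribution of values, so such lists would shift little however dim array 1 was. The pooled markers thus differed more than other genes of their wild-type level, but the dimmer signal stays open as a source. Proliferation genes (49 of 51 higher, median 0.57), Notch genes (0.54), hox genes (0.52), endoderm markers (0.77) and neural crest markers (0.60) also lay higher on array 2, and sarcomere genes (-0.38), pericardial (-0.35), endothelial (-0.36) and blood markers (-0.31) lower. A difference in stage or BMP dose between the pools was not tested and stays open, and krt8 and krt18a.1 are in both the epidermal and the pericardial list.

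Among probes called at least 8-fold changed, 18 were lower, 7 of them named, and 14 were higher, 13 of them named, with clu, ved, igfbp1a and zgc:163030 among these by 2 probes each. Of the 18, 44.4% lay above background on both Bmp2b arrays. A low share was set beforehand as the outcome for loss at the floor of these dimmer arrays, and 44.4% met it. A true fall gives such a share too, so it decides nothing. A floor can only shrink a fall. With values raised to it the 18 probes kept a fall of at least 2.35 log2 units, or 5.08-fold to 199-fold (largest SE 0.35 log2 units). As the probes were chosen for an 8-fold fall, a fall had to remain, so this bounds each fall but is no test of the floor as the source. A probe or transcript variant between the fish lines may remove the signal of single probes. It cannot be told apart from a loss of the transcript, since 3 of the 18 had another tested probe of the same gene. Among the named ones, lft1, tmem88a, atp8b5a and mhc1lia had no other tested probe. For probes called at least 4-fold lower, the median of the gene's other probes lay within 2-fold of wild type in 29 of 54 (median -0.87). For probes at least 4-fold higher it did in 16 of 43 (median 1.63). These are counts of probes, and a gene with several such probes enters for each of them.

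Heat shock genes were lower in hearts that carried a heat shock transgene. The list's median was -0.57 on Bmp2b array 1, so the fall was not confined to array 2, and surrounding tissue on array 2 alone cannot account for it. Array 1 also differed from wild type in neural markers (median -0.84), so a difference in tissue make-up is not excluded. Hearts taken later within the stated window may hold less of the induced transcripts, and sarcomere genes, which rise with stage, had a median of -0.35. That median was -0.12 on Bmp2b array 1 and -0.50 on array 2. As the transgene could itself lower sarcomere genes, later sampling and an effect of Bmp2b cannot be told apart here.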
